A study of Homo sapiens with 30 samples.

How the data were processed

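The series holds 30 samples of human G401 cells in culture, and groups were taken from the labels. RNA-seq (12 samples, 24 h) compared parental and DTMYC cells, each in DMSO and in 500 nM dTAG47, with 3 samples per group. PRO-seq (4 samples, 4 h), ATAC-seq (6 samples, 24 h) and ChIP-seq (8 samples, 4 h) were from DTMYC cells. Of the ChIP-seq samples 3 were IgG controls, which were not analysed here. The MYC ChIP-seq samples in DMSO are numbered 1 and 3. Their labels name MYC as the antibody, whereas the names of the deposited peak lists say HA, the tag carried by the MYC fusion. RNA-seq followed depletion of ribosomal RNA.

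The submitters' processing notes name STAR, featureCounts, DESeq2, Bowtie2, MACS2, DiffBind and cutadapt and the genome build hg19, and their versions and roles are not given in the sources used here. For RNA-seq the authors deposited a table of raw read counts per gene, whose values are whole numbers, with 18132 entries. For PRO-seq the authors deposited read counts per gene for promoter-proximal regions and for gene bodies, with 20582 entries. The table also holds a gene body density that the authors made, before they deposited it, by dividing the gene body count by a length, with no scaling for depth, and it was used here only to work out that length. In 17655 of 17688 entries the gene body length equals the gene's span minus 999 bases. For ChIP-seq and ATAC-seq the deposited lists give each peak a score, which is 10 times the −log10 q value as MACS2 writes it, called for each sample alone. The lowest score was 13 in every list but one of 7 peaks, and the lists have no column for summits, so the midpoint of a region was used where a summit had been planned.

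The reference sequence was GRCh37, the same build as hg19, with GENCODE v44 lifted to it, and no peak lay beyond the end of a chromosome. A table of GRCh38 genes was not used for coordinates. In RNA-seq 97.55% of the entries on the numbered chromosomes and X matched a GENCODE gene by identifier and overlapped its position. Symbols were matched through older names, 301 symbols had several entries, and 580 entries lay on patch or haplotype contigs.

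RNA-seq totals ranged from 27854207 to 54633745 counts per library. PRO-seq totals ranged from 18209879 to 23256313 counts in gene bodies and from 1216928 to 1632084 in promoter-proximal regions. The common biological coefficient of variation was 0.121 in RNA-seq and 0.126 in PRO-seq gene bodies. The read depth behind the peak lists is unknown.

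Counts were tested with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr by group, TMM normalisation, and the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 12 RNA-seq libraries entered a single fit with 4 contrasts, which were dTAG47 against DMSO within each line, the difference of these responses (the interaction), and DTMYC against parental cells in DMSO. PRO-seq gene bodies and promoter-proximal regions were fitted separately. The pausing test was the interaction of region and treatment with the library as a block and the gene body normalisation for both regions. No replicate block was used in the main fits. Levels are given in CPM with effective library sizes, and the log2 fold changes are those of the edgeR fit. The log2 CPM values behind correlations between libraries and offsets use a prior count of 2.

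The 31 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named below as added. Each list was tested against all other genes with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the lists, and again with an estimated correlation. Counts adjusted over the list alone take the edgeR p-values of the list's genes. The fry test asks whether the genes of a list move, on balance, one way, and compares with no other gene. The lists of haematopoietic, kidney epithelial and neuronal markers stood for other cell types.

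The rule for named genes takes the 8 genes with the largest rise and the 8 with the largest fall in DTMYC cells and in gene bodies (5 and 5 elsewhere) among those past the threshold, with at least 5 CPM on average (50 counts in PRO-seq) and every library of one group above every library of the other. It adds up to 4 members per list past the threshold with the smallest adjusted p (or the 2 most abundant where none passed) and MYC, MAX, SMARCB1, SMARCA4, MYCN and CDKN1A. Genes with near-identical copies are named as uncertain. In PRO-seq no gene met the rule, so those with the smallest unadjusted p were named after their values were seen.

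A MYC region was the union of overlapping peaks (at least 1 base) of both DMSO libraries. Regions were compared with bedtools 2.31.1, and a gene was called bound when a region's midpoint lay within 1000 bases of one of its start sites. CACGTG was searched within 100 bases of midpoints on the numbered chromosomes and X, and at positions 10000 bases to each side. Intervals of shares are Clopper-Pearson intervals at 95%. Numbers of peaks and Jaccard indices were compared by exact permutation tests in scipy 1.17.1 under Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. ATAC-seq regions counted as open in a group when at least 2 of 3 libraries had a peak.

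GC content of genes came from the reference, with values for 97.3% of the genes tested in RNA-seq. Gene length came from the deposited table of RNA-seq counts. Both were used for offsets per library, fitted as splines with 5 degrees of freedom. Folds against groups with no counts use a floor of 3 counts over the group.

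The fits were tested on simulated data made from the libraries themselves with 200 changed genes. The edgeR test recovered 74.6% of 2-fold changes within DTMYC cells, 71.6% for the interaction, 68.7% in PRO-seq gene bodies, 47.8% in promoter-proximal regions and 5.97% for pausing. For 1.5-fold changes these shares were 61.2% in DTMYC cells, 17.9% for the interaction and 34.3% in gene bodies. Unchanged genes made up 3.16% of the edgeR calls in DTMYC cells, 7.98% in parental cells, 9.30% for the interaction and 11.1% in gene bodies, and 14.6%, 17.1% and 14.8% of the DESeq2 calls in DTMYC cells, the interaction and gene bodies. Of 6 lists of 50 genes shifted 1.25-fold among 31, the preset camera found 6 in RNA-seq and 6 in PRO-seq. The estimated correlation found 6 and 0. Genes were drawn independently of each other, so these data do not test the preset where genes of a list move together. They also hold no deviation that many genes of a library share, such as that of parental DMSO library 3 described below. The shares of unchanged genes among the calls thus do not cover such deviations, which bear on the parental and interaction calls.

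The alternatives fixed in advance were DESeq2 size factors, total counts alone, the DESeq2 1.42.0 Wald test, no filter, a filter at 1 CPM, the replicate number as a block, only the 6 libraries of a contrast, minimum folds of 2 (RNA-seq) and 1.5 (PRO-seq), each library left out, camera with an estimated correlation and fry. For peaks they were −log10 q of at least 5 or 10, a reciprocal overlap of 50%, start site distances of 250 and 5000 bases, and other definitions of shared regions. Offsets for GC content, the DTMYC contrast without parental DMSO library 3, and PRO-seq genes at an unadjusted p under 0.05 were added after seeing the data. An alternative is said to keep a tested result when direction and side of the threshold are the same. A result that passed in neither fit also counts as kept, whatever its direction. A count is kept when it is within 1.5 times the main count. A value with no test is kept when it moves by less than the SD between replicates or its binomial interval.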

Results

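The data came from G401 cells, an established malignant rhabdoid tumour line, and from a G401 derivative named DTMYC. In DTMYC cells the endogenous MYC gene had been removed by CRISPR editing, and a lentivirus supplied MYC fused to a tag that the compound dTAG47 binds. dTAG47 brings proteins carrying this tag to the ubiquitin system for degradation, and DMSO is its solvent. The labels give 30 samples in all, and every treatment was at 500 nM dTAG47. MYC ChIP-seq maps the sites that MYC occupies on chromatin, and it was available after 4 h from 2 DMSO and 3 dTAG47 libraries of DTMYC cells. PRO-seq, which counts engaged RNA polymerases, covered 2 DMSO and 2 dTAG47 libraries at 4 h. ATAC-seq, which maps open chromatin, covered 3 DMSO and 3 dTAG47 libraries at 24 h. RNA-seq covered 4 groups of 3 libraries at 24 h, with parental and DTMYC cells each in DMSO and in dTAG47. The RNA-seq libraries held between 27854207 and 54633745 counts in genes. The PRO-seq libraries held between 18209879 and 23256313 counts in gene bodies and between 1216928 and 1632084 in promoter-proximal regions. The depth of the peak data is unknown, because the peak lists give no read counts. Intervals and floors cover counting error only. The p-values measure only the spread between these libraries, since the labels do not say that the replicates were separate cultures.

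The ChIP-seq comparison asks how far MYC leaves its sites within 4 h of dTAG47. The DMSO libraries numbered 1 and 3 had 4010 and 1519 MYC peaks, and the dTAG47 libraries had 408, 7 and 193. The mean was 2764.5 ± 1761.4 peaks in DMSO (SD, n = 2) and 202.67 ± 200.67 peaks after dTAG47 (SD, n = 3). Every dTAG47 library lay below every DMSO library, and the exact permutation test gave a two-sided p of 0.1, the smallest that 10 splits can give. In DMSO, 1068 regions had a peak in both libraries, and 80.6% of these (binomial 95% interval 78.1 to 82.9, Clopper-Pearson) had their midpoint within 1000 bases of an annotated start site. The E-box CACGTG, the sequence that MYC and its partner MAX bind, lay within 100 bases of the midpoint in 26.4% of them (23.8 to 29.2), against 2.04% (1.48 to 2.75) of flanking positions 10000 bases away.

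Regions of both DMSO libraries were ordered by the lower of their DMSO scores, in hg19 coordinates. The strongest on numbered chromosomes lay outside protein-coding genes, on chromosome 7. One ran from 45025633 to 45026565 with scores of 954 and 549 (nearest protein-coding start site MYO1G). The other ran from 4681367 to 4682208 with scores of 1265 and 501 (nearest FOXK1). Non-coding genes at these positions were not examined. Regions at the start sites of BRWD1 and of SNX5 (827 and 384) followed. Start sites of protein-coding growth genes lay further down, and those named next were chosen after their values were seen. A region on chromosome 10 from 103892754 to 103893805 lay in an intron of PPRC1, a coactivator of mitochondrial biogenesis, with scores of 891 and 326 and 5 copies of CACGTG. The region on chromosome 5 from 170814475 to 170815886 lay in an intron of NPM1, a nucleolar chaperone of ribosome assembly, with scores of 573 and 294. The region on chromosome 17 from 49230641 to 49231523 covered the untranslated start of NME1, a nucleoside diphosphate kinase, with scores of 729 and 293 and the site CGTCCCACGCCACGTGGACTCGCCTT at 49231193. MAT2A, which makes S-adenosylmethionine, had its region on chromosome 2 from 85765520 to 85767270, and these 4 regions kept a peak in dTAG47 libraries 1 and 3. RPS19, a ribosomal protein gene, had a region on chromosome 19 from 42364013 to 42364987 that kept no peak in any dTAG47 library. Of the 1068 regions, dTAG47 library 1 still had a peak in 22.7% (20.2 to 25.3), library 2 in 0, which allows a share of up to 0.345%, and library 3 in 9.83% (8.11 to 11.8). The mean of these shares was 10.8 ± 11.4% (SD, n = 3). It was 5.52% when a reciprocal overlap of 50% was required, 7.59% without DMSO library 1 and 3.62% without DMSO library 3. The 7 peaks of dTAG47 library 2 all lay within 1 Mb of an assembly gap, and none had a CACGTG near its midpoint. The lowest score of this library was 123, against 13 in every other list. Its 0 cannot be told apart from a sample without usable signal. Regions that kept a peak in library 1 had a median DMSO score of 97.5, against 50 for those that did not, taking the lower of the DMSO scores, and in library 3 these medians were 130 and 54. The 2 DMSO libraries differed in peak number, and 26.8% of the peaks of DMSO library 1 overlapped a peak of DMSO library 3. Some of the highest scores in both DMSO libraries lay on an unplaced contig.

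**Figure D1:**
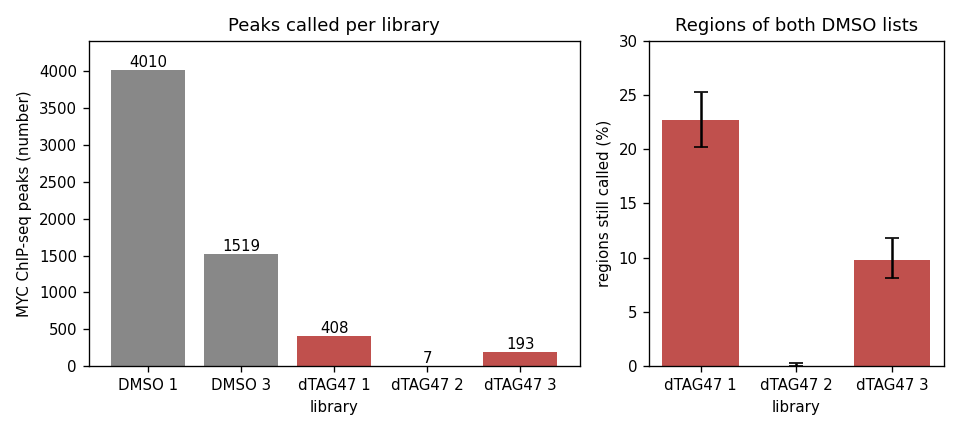
The left panel shows the number of MYC ChIP-seq peaks in each library of DTMYC cells (grey, DMSO; red, dTAG47 for 4 h), and the right panel the percentage of the 1068 regions of both DMSO lists that still had a peak in each dTAG47 library, with bars for the binomial 95% interval. The dTAG47 libraries had 408, 7 and 193 peaks, below the 4010 and 1519 of the DMSO libraries.

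RNA-seq of DTMYC cells asks which mRNAs change when MYC has been degraded for 24 h. Of 78 ribosome biogenesis genes 38 fell, and of 29 extracellular matrix and adhesion genes 5 rose. In edgeR, 572 genes rose and 595 fell out of 13401 tested, at an adjusted p under 0.05. The changes were modest, since 65 genes moved at least 2-fold. With only the 6 DTMYC libraries in the fit 2084 genes rose and 2509 fell. With offsets for GC content and length 1362 rose and 1993 fell. MYC mRNA itself was at 1401 ± 63.3 CPM (counts scaled to library size; SD, n = 3) after dTAG47 against 1370 ± 49.7 in DMSO, a log2 change of 0.05 ± 0.08 (SE) with an adjusted p of 0.801. MAX, the DNA-binding partner of MYC, fell by 0.30 ± 0.07 on the log2 scale.

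Among genes with at least 5 CPM on average and no overlap between the groups, the largest fall was that of DDN, which encodes a dendrite protein (chromosome 12, 49388932 to 49393092, hg19), from 17.7 ± 0.828 to 7.03 ± 0.160 CPM, a log2 change of −1.32 ± 0.10 with an adjusted p of 9.54e-05. TERT, the catalytic subunit of telomerase (chromosome 5, 1253262 to 1295184), fell from 17.4 ± 1.83 to 7.77 ± 0.513 CPM, with a log2 change of −1.15 ± 0.15 and an adjusted p of 0.00143. MATK, a tyrosine kinase that restrains SRC family kinases, had a log2 change of −1.16 ± 0.11. DUSP2, a phosphatase of MAP kinases, had a log2 change of −1.14 and NEFH, the heavy neurofilament chain, one of −1.04. KLF15, FABP5 and P2RX5 followed with log2 changes of −0.95, −0.93 and −0.90, and FABP5 shares reads with near-identical copies, so its value is uncertain. PLCB2, a phospholipase of G-protein signalling (chromosome 15, 40570377 to 40600136), rose most among genes chosen in the same way, from 12.8 ± 1.30 to 25.8 ± 1.64 CPM, a log2 change of 1.03 ± 0.10 with an adjusted p of 2.78e-04. APOLD1, KIAA0319, FAM114A1, LIMS2 and APOL2 rose with log2 changes of 1.03, 1.01, 1.00, 0.99 and 0.98. CD82, a tetraspanin that restrains cell migration, rose by 0.90, and ZNF117, a zinc-finger gene with near-identical copies whose value is uncertain, by 0.92. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, had a log2 change of 0.11 with an adjusted p of 0.498, and SMARCA4, the ATPase of the SWI/SNF remodeller, one of −0.06 with an adjusted p of 0.735. MYCN had no counts in any DTMYC library.

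Among 31 gene lists, 23 shifted by limma's camera test with its preset correlation, and 14 of these calls held with an estimated correlation, which gave the highest adjusted p of any alternative for every list called in RNA-seq. Of 56 canonical MYC targets, 38 fell and none rose (47 fell when adjusted over the list alone), with a median log2 change of −0.41 and an adjusted p of 1.13e-31 (0.00437 with an estimated correlation). They included SLC19A1, the folate carrier, at −0.68 and SORD, sorbitol dehydrogenase, at −0.56. Of 78 ribosome biogenesis genes, 38 fell (49 adjusted over the list alone), with a median of −0.36 and an adjusted p of 0.00264 with an estimated correlation. IMP4, NOP16 and NOP56, which process ribosomal RNA, had log2 changes of −0.67, −0.64 and −0.57. Of 33 genes of the RNA polymerase I and III machinery, 9 fell (12 adjusted over the list alone), among them CD3EAP at −0.65 and POLR1B at −0.58, with an adjusted p of 0.00506 with an estimated correlation. Translation factors had a median of −0.20, and 7 of 42 fell (12 adjusted over the list alone; adjusted p = 0.00437 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases had a median of −0.12, and KARS and FARSA, 2 of 21, fell, with the same 2 adjusted over the list alone (adjusted p = 0.0248 with an estimated correlation). Of 74 cytosolic ribosomal protein genes none passed the edgeR test, although 72 had a negative change and the median was −0.17. Their adjusted p was 3.10e-11 with the preset and 0.120 with an estimated correlation.

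Mitochondrial and metabolic lists moved the same way. Mitochondrial import genes and chaperones had a median of −0.33 with 9 of 27 falling (14 fell and 1 rose adjusted over the list alone; adjusted p = 0.00506 with an estimated correlation), led by GRPEL1 at −0.55 and TRAP1 at −0.59. Of 74 mitochondrial ribosomal protein genes, 13 fell (18 adjusted over the list alone; adjusted p = 0.0216 with an estimated correlation), among them MRPL36 at −0.53. Of 28 genes of purine and pyrimidine synthesis, 11 fell, also when adjusted over the list alone, including IMPDH2 at −0.51, IMPDH1 at −0.65 and GART at −0.40 (adjusted p = 0.0108 with an estimated correlation). In serine and one-carbon metabolism 6 of 20 genes fell and 1 rose (9 and 2 adjusted over the list alone; adjusted p = 0.0165 with an estimated correlation). GLDC, which cleaves glycine, was at −0.56, and SLC1A4, a transporter of neutral amino acids, at 0.56. Cytosolic chaperones fell in 6 of 24 cases (13 adjusted over the list alone; adjusted p = 0.0165 with an estimated correlation), with FKBP4 at −0.63. In cholesterol synthesis 5 of 22 genes fell and TM7SF2, a sterol reductase, rose by 0.67. The counts were the same adjusted over the list alone (limma's adjusted p = 0.0216 with an estimated correlation). This list also fell in parental cells, which carry no degradable MYC, so its fall is not particular to DTMYC cells. In the glycolysis list HK2, the first enzyme of the pathway, was among 4 of 22 that fell, at −0.49, and the glucose transporter SLC2A3 rose by 0.36 (6 and 2 adjusted over the list alone; adjusted p = 0.218 with an estimated correlation). Of 15 polyamine genes the synthetic enzymes SRM and ODC1 fell by 0.52 and 0.33 (3 genes adjusted over the list alone; adjusted p = 0.120 with an estimated correlation). None of 69 oxidative phosphorylation genes passed the edgeR test, adjusted over the list alone or over all genes. Their median was −0.09 (limma's adjusted p = 0.361 with an estimated correlation). Negative medians in parental cells too, as given below, were those of oxidative phosphorylation, cytosolic and mitochondrial ribosomal proteins, mitochondrial import and translation factors.

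In the growth control lists, 5 of 47 DNA replication genes fell, including MCM7 at −0.32 (6 adjusted over the list alone; adjusted p = 0.0108 with an estimated correlation). Of 20 MYC network members, 4 fell (5 adjusted over the list alone), among them MXI1 at −0.54 and RUVBL2 at −0.34 (adjusted p = 0.0255 with an estimated correlation). CDKN2B and CDKN2C, inhibitors of CDK4 and CDK6, were the 2 of 8 CDK inhibitor genes that rose, by 0.82 and 0.47, also when adjusted over the list alone (adjusted p = 0.108 with an estimated correlation). Of 29 p53 targets 5 fell, with BBC3, a promoter of apoptosis, at −0.40 (5 fell and 2 rose adjusted over the list alone; adjusted p = 0.0697 with an estimated correlation). In the integrated stress response list 4 of 24 genes fell and 1 rose (6 and 1 adjusted over the list alone), with the amino acid transporter SLC7A5 at −0.56 and NUPR1 at 0.50 (adjusted p = 0.108 with an estimated correlation). Extracellular matrix and adhesion genes had a median of 0.25, and 5 of 29 rose, also when adjusted over the list alone, among them THBS1 at 0.99 and COL5A2 at 0.54 (adjusted p = 0.0286 with an estimated correlation). Of 22 interferon response genes 4 rose, namely DDX58, STAT2, IFI35 and IRF1 at 0.75, 0.66, 0.58 and 0.36, and 7 rose adjusted over the list alone. The median of this list was 0.47, with an adjusted p of 0.0510 with an estimated correlation. Of 36 lysosome and autophagy genes 3 rose, including GABARAPL1 at 0.50 (4 adjusted over the list alone; adjusted p = 0.424 with an estimated correlation). The 8 lists not called were G1 to S cyclins and E2Fs (20 genes, adjusted p 0.0710, with TFDP1 at −0.42), neuronal markers (6 genes, 0.0947), immediate early genes (26 genes, 0.0980), kidney epithelial markers (11 genes, 0.270, with 3 higher adjusted over the list alone), haematopoietic markers (2 genes, 0.448), SWI/SNF subunits (23 genes, 0.572), MHC class I presentation (8 genes, 0.809, with a positive median and a negative mean) and mitosis (50 genes, 0.967). Without any one of the 6 DTMYC libraries the number of genes called lay between 329 and 636, and without parental DMSO library 3, which stood apart from its group, it was 3951 and included all 1167.

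**Figure D2:**
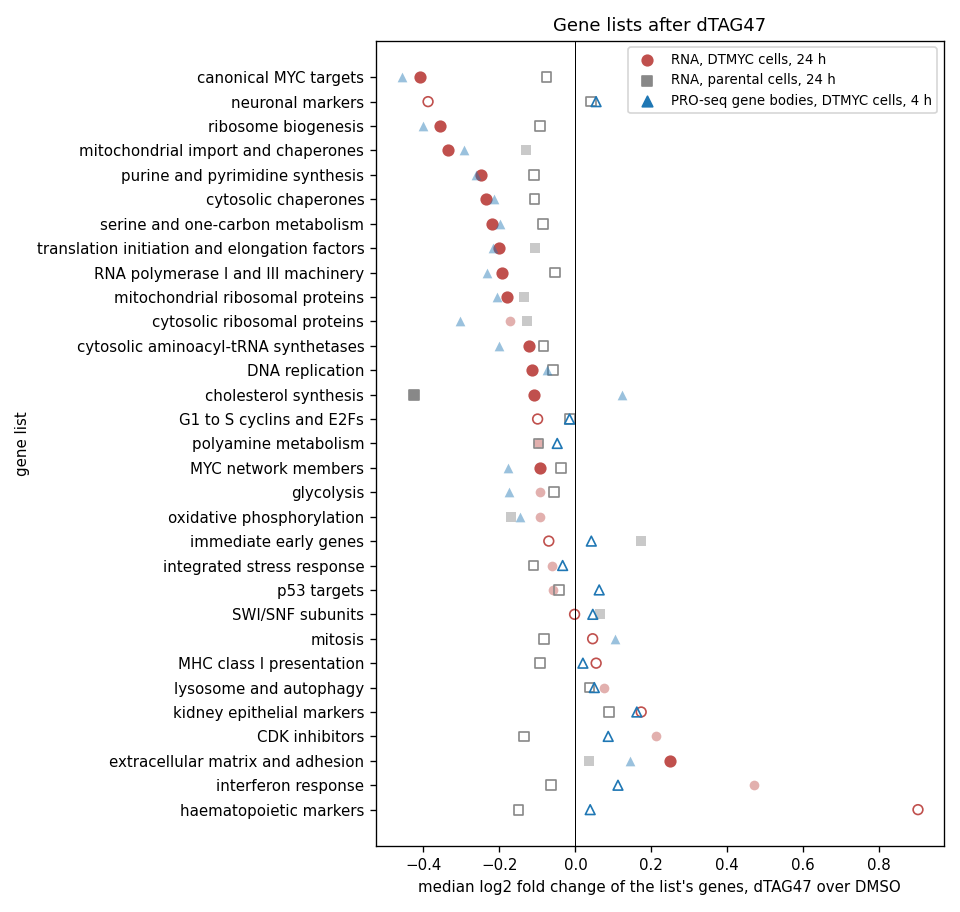
Each marker gives the median log2 fold change, dTAG47 over DMSO, of the tested genes of a list (circles, RNA-seq of DTMYC cells at 24 h; squares, RNA-seq of parental cells at 24 h; triangles, PRO-seq gene bodies of DTMYC cells at 4 h). Full colour marks calls that held with an estimated correlation, pale colour calls with the preset correlation only and open markers lists not called; canonical MYC targets lay at −0.41, −0.08 and −0.46.

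Parental cells carry no degradable MYC and serve as a control for effects of dTAG47 itself. In these cells 14 genes rose and 3 fell out of 13401 tested. POM121C, a nuclear pore gene (chromosome 7, 75046066 to 75115548, hg19) with near-identical copies, rose from 13.4 ± 0.772 to 26.6 ± 0.674 CPM (SD, n = 3), a log2 change of 0.99 ± 0.12 with an adjusted p of 0.009, and its value is uncertain. TMEM173, which encodes STING, rose by 0.74, SHISA3 by 0.66, METAP1D by 0.64 and SCUBE3 by 0.63. The genes that fell were SERPINF2 at −0.92, CCNG1, a p53-induced cyclin, at −0.60 and FDFT1, the squalene synthase of cholesterol synthesis, at −0.50 with an adjusted p of 0.0338. MYC mRNA was 235 ± 8.81 CPM after dTAG47 and 235 ± 29.2 in DMSO.

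Cholesterol synthesis was the list that moved clearly in parental cells. All 22 tested genes had a negative change with a median of −0.42, FDFT1 passed over all genes, 17 fell when adjusted over the list alone, and the adjusted p was 4.60e-16 (4.19e-04 with an estimated correlation). A further 8 lists were called with the preset correlation and lost with the estimated one. Immediate early genes had a median of 0.17 with DUSP6, a MAP kinase phosphatase, rising by 0.51 (5 of 26 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation). Oxidative phosphorylation had a median of −0.17, cytosolic ribosomal proteins −0.13, mitochondrial ribosomal proteins −0.13, mitochondrial import −0.13 and translation factors −0.11, and with an estimated correlation their adjusted p-values were 0.351, 0.382, 0.158, 0.158 and 0.107. SWI/SNF subunits had a median of 0.07 and extracellular matrix genes one of 0.04, with adjusted p-values of 0.158 and 0.232 with an estimated correlation. Canonical MYC targets and ribosome biogenesis genes had medians of −0.08 and −0.09 and were not called, each with an adjusted p of 0.0556. Parental DMSO library 3 had a mean correlation of 0.982 with the other libraries of its group, where those of the other 3 groups were at 0.995 or above, and its deviations from its group followed GC content with a Spearman's rho of −0.74. Across genes, the parental change followed GC content with a rho of 0.33, and the fifth of genes with the least GC had a median change of −0.25. The count of 17 depended on single libraries, being 3, 353 and 2718 without DMSO library 1, 2 and 3 and 0 without any one of the dTAG47 libraries, and it was 310 in DESeq2. The excess of rises was not kept everywhere, with 167 rising and 143 falling in DESeq2, 1240 and 1478 without DMSO library 3, and 325 and 399 with offsets for GC content and length. With effective library sizes scaled by the DESeq2 factors 7 genes were called, and with total counts alone 71 rose and 14 fell.

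The interaction test asks whether DTMYC cells respond to dTAG47 differently from parental cells. In edgeR 159 genes differed, 80 with a higher and 79 with a lower response in DTMYC cells, and with DESeq2 size factors these were 38 and 25. DDN, NEFH, TERT and MATK responded lower in DTMYC cells, with differences of −1.20 ± 0.13, −1.12 ± 0.13, −1.04 ± 0.22 and −0.92 ± 0.15 on the log2 scale. TM7SF2 responded higher by 1.07 ± 0.14 and TJP3, a tight junction protein, by 1.33 ± 0.24. C7orf60 was higher by 1.20. ZNF117 and SULT1A1, both with near-identical copies and so uncertain, were higher by 1.48 and 1.42, and POM121C, likewise uncertain, was lower by a difference of −1.33. In parental cells NEFH was at 201 ± 2.38 CPM after dTAG47 and 190 ± 26.0 in DMSO.

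Lists of growth genes responded lower in DTMYC cells. Cholesterol synthesis, which fell in both lines, responded higher, meaning that it fell less in DTMYC cells. Canonical MYC targets had a median difference of −0.36, with 8 of 56 genes lower (26 adjusted over the list alone) and an adjusted p of 1.71e-18 (0.0358 with an estimated correlation). These 8 included MYBBP1A at −0.76 and TCOF1, a factor of ribosomal RNA transcription, at −0.62. Ribosome biogenesis genes had a median of −0.30, with 5 of 78 lower (31 adjusted over the list alone; adjusted p = 0.0238 with an estimated correlation), among them RRP1B at −0.67. RNA polymerase I and III genes had a median of −0.17, with none passing over all genes and 2 adjusted over the list alone (adjusted p = 0.0404 with an estimated correlation). Cholesterol synthesis was higher with a median of 0.25, and TM7SF2 and ACAT2 passed (3 genes adjusted over the list alone; adjusted p = 0.0404 with an estimated correlation). These 4 calls held with the estimated correlation, and 12 others were lost. Among those lost were mitochondrial ribosomal proteins, with a median difference of −0.0259 (limma's adjusted p = 0.382 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases were not called for the interaction, and limma's lowest adjusted p over the alternatives was 0.140. The difference followed GC content across genes with a rho of −0.31, and the fifth of genes with the least GC had a median of 0.32. The count was 549 and 2417 without parental DMSO library 2 and 3, between 5 and 28 without any one parental dTAG47 or DTMYC library, and 555 in DESeq2.

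**Figure D3:**
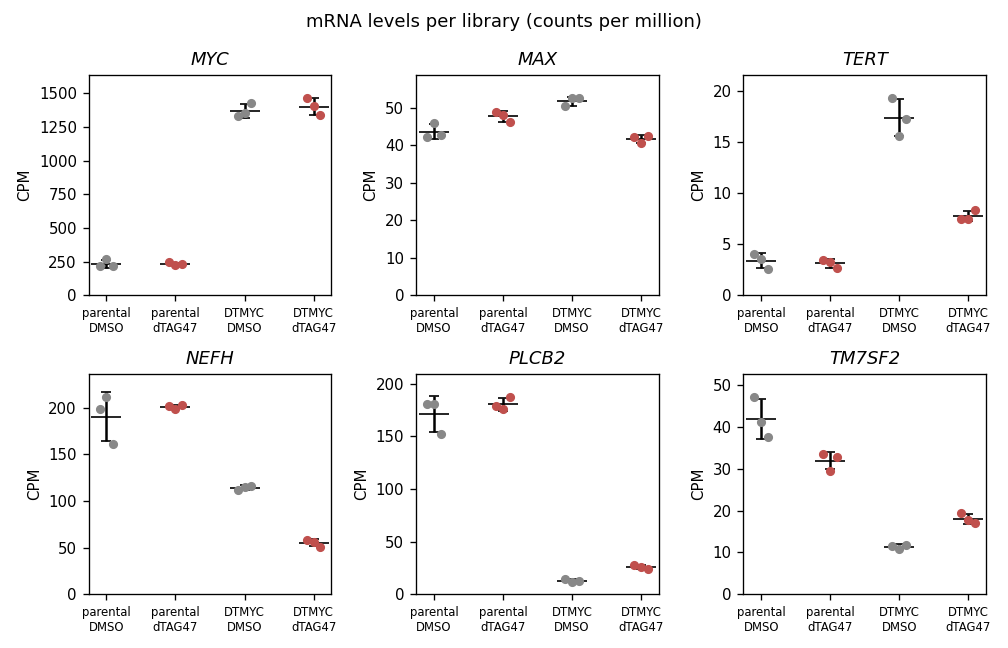
Each point is the level of an mRNA in 1 RNA-seq library, in CPM, for parental and DTMYC cells in DMSO (grey) or dTAG47 (red); lines mark the mean and bars the SD of 3 libraries. MYC was near 235 CPM in parental and between 1370 and 1401 CPM in DTMYC cells, while TERT in DTMYC cells went from 17.4 to 7.77 CPM.

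The DMSO baseline shows how the derivative differs from parental cells before any degradation. MYC mRNA was 5.82-fold higher in DTMYC cells, at 1370 ± 49.7 against 235 ± 29.2 CPM (SD, n = 3), with an adjusted p of 1.23e-10. In all, 4819 genes were higher and 4999 lower out of 13401. S100A10, a partner of annexins (chromosome 1, 151955391 to 151966866, hg19), was higher by 8.30 ± 0.19 on the log2 scale, DLK1, an inhibitor of differentiation, by 7.26, FLRT2 by 7.01, ST18 by 6.76 and NPR1, the receptor of natriuretic peptides, by 6.63. Several genes had no count in the DTMYC DMSO libraries. Against a floor of 3 counts over the group, the phospholipid transporter ATP10A (chromosome 15, 25922420 to 26110317) was at least 4045-fold lower, ARID5B at least 1740-fold lower, NTNG1 at least 1662-fold lower and EGFL6 at least 702-fold lower. GABRA5, a subunit of the GABA receptor, had 3 counts against 24268, a ratio of 6592 (counting interval 2255 to 31969). CCND2, a D-type cyclin, was lower by a log2 change of −8.20 and the glucose transporter SLC2A3 higher by 2.94.

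Ribosome biogenesis genes were higher in DTMYC cells with a median log2 difference of 0.65, with 59 of 78 higher and 4 lower (60 and 4 adjusted over the list alone), among them RRP15 at 1.89 and HEATR1 at 1.58. Canonical MYC targets had a median of 0.38, with 35 of 56 higher and 8 lower, the same adjusted over the list alone. Interferon response genes had a median of −1.44, with 16 of 22 lower and 3 higher, also when adjusted over the list alone, including IFIT1 at −6.40 and STAT2 at −1.08. Oxidative phosphorylation genes had a median of −0.63 and cytosolic ribosomal proteins one of −0.48. Targets of p53 had a median of 0.41, with PERP at 2.73. These 6 lists were called with the preset correlation, and with an estimated correlation the adjusted p was 0.155 for ribosome biogenesis, 0.625 for canonical MYC targets, 0.250 for interferon response, 0.625 for oxidative phosphorylation, 0.630 for cytosolic ribosomal proteins and 0.237 for p53 targets. GC content ran with these groups, since the baseline difference followed it across genes with a rho of −0.44 and 5 equal groups of genes from least to most GC had medians of 0.68, 0.41, −0.09, −0.39 and −0.45. Of the 9818 genes, 77.6% were called in the same direction after offsets for GC content and length.

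PRO-seq asks which genes change in transcription within 4 h. In edgeR without a replicate block no gene passed in gene bodies out of 13397. At an unadjusted p under 0.05, 505 were higher and 793 lower, 1298 in all against 670 by chance. DESeq2 called 67, of which 61 fell. With the replicate number as a block edgeR called 4360 gene bodies, 2226 higher and 2134 lower, and 262 promoter-proximal regions. The count of 0 thus depended on leaving out the block, and the labels do not say what the numbers share. In promoter-proximal regions no gene passed out of 10226, with 661 at an unadjusted p under 0.05 and 2 called by DESeq2. Among gene bodies with the smallest unadjusted p, chosen after their values were seen, MATK had a log2 change of −1.18 and an adjusted p of 0.357, LAMC3, a laminin chain, one of −0.87 and ECE2 one of −0.84. NPM1 was at −0.49 ± 0.13 (SE, n = 2) with an adjusted p of 0.430, MAX at −0.29 and MYC at 0.01 ± 0.20. The pausing comparison, the change of promoter-proximal against gene body counts, called no gene out of 13286 in edgeR, with 269 at an unadjusted p under 0.05 against 664 by chance, and limma on the log2 ratio called 0 with 546 at an unadjusted p under 0.05. Its median was −0.16 with gene body scaling and 0.02 with each region scaled on its own, so its direction depended on the scaling, and without any one library it lay between −0.38 and 0.03. The promoter-proximal median was 0.01 with TMM and −0.18 with total counts alone. Without any one library the gene body test called between 5 and 44 genes and the promoter-proximal test between 1 and 5.

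With the preset correlation 15 gene lists were lower and 3 higher in PRO-seq gene bodies. Ribosome biogenesis genes had a median of −0.40, with 74 of 76 negative, no gene passing over all genes and 45 falling when adjusted over the list alone. Canonical MYC targets had a median of −0.46, with all 54 negative and 32 falling when adjusted over the list alone. Cytosolic ribosomal proteins had a median of −0.31, with all 68 negative and none passing. Lists of purine and pyrimidine synthesis, mitochondrial import, RNA polymerase I and III, translation factors, chaperones, mitochondrial ribosomal proteins, tRNA synthetases, serine metabolism, MYC network, glycolysis, oxidative phosphorylation and DNA replication were lower, with medians from −0.29 to −0.08. Adjusted over the list alone, 6 genes each of purine and pyrimidine synthesis and of serine metabolism fell, 5 of the RNA polymerase I and III machinery, 2 of mitochondrial import and 1 translation factor. Mitosis, cholesterol synthesis and extracellular matrix were higher, with medians of 0.11, 0.12 and 0.14, whereas cholesterol synthesis was lower in DTMYC mRNA at 24 h. With no filter on counts 0 lists were called higher, and mitosis and cholesterol synthesis turned to lower without DMSO library 2 or without dTAG47 library 1. None of these 18 calls with the preset correlation held with an estimated correlation, where the adjusted p was 0.488 for all but DNA replication (0.708), cholesterol synthesis (0.684) and mitosis (0.763). In simulated data the estimated correlation found 0 of 6 shifted lists with 2 libraries per group, and the preset 6 of 6. Those genes were drawn independently, so this cannot show whether the preset calls hold where genes of a list move together.

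Nascent and mRNA changes went together in DTMYC cells. Across 11150 genes tested in both assays, Spearman's rho was 0.636 and Pearson's r 0.532 with the DTMYC mRNA change, against 0.0877 and 0.0633 with the parental change, where genes are not independent replicates. Of 549 genes whose mRNA fell, 97.3% had a negative PRO-seq change, and of 527 whose mRNA rose, 92.0% had a positive one. The overlap of called genes could not be taken from the main edgeR fit, which called 0 genes in PRO-seq. With DESeq2 in both assays, 43 of the 54 genes lower in PRO-seq also fell in mRNA, where 2.46 would be met by chance, and 4 of the 5 higher ones also rose, against 0.215.

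**Figure D4:**
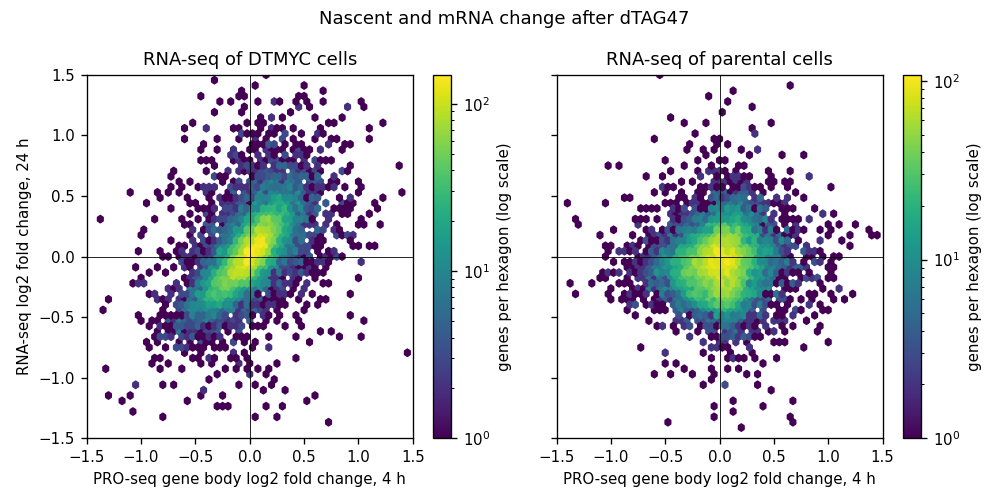
Hexagons count genes by PRO-seq gene body log2 fold change at 4 h (x axis) and RNA-seq log2 fold change at 24 h (y axis) of DTMYC cells (left) and parental cells (right), with a log colour scale; 46 and 18 of the 11150 genes lie outside the axes. Spearman's rho across genes was 0.636 on the left and 0.0877 on the right.

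Genes with a MYC peak near their start site in both DMSO libraries were then set against the others. Of 993 such genes tested in RNA-seq, 16.3% fell and 0.906% rose in DTMYC cells, against 3.49% and 4.54% of the 12408 others. Their median change lay lower by a difference of −0.20, and limma's camera gave p = 6.74e-17 with the preset and p = 8.02e-04 with an estimated correlation. In PRO-seq the difference was −0.22 over 948 genes, with p = 1.71e-26 and, with an estimated correlation, p = 0.149. In parental cells the difference was −0.05 and for the interaction it was −0.14, and limma's camera gave p = 0.00437 and p = 5.08e-07 with the preset correlation. In DMSO the bound genes were higher in DTMYC than in parental cells by a difference of 0.29, with limma's camera at p = 1.35e-04 and the preset correlation. Bound genes made up 7.41% of all genes tested, 57 of 74 cytosolic ribosomal proteins (odds ratio 44.3, Fisher's exact test, adjusted p = 1.75e-48), 39 of 56 canonical MYC targets and 42 of 78 ribosome biogenesis genes. In all 12 of the 31 lists held more bound genes than the rest at an adjusted p under 0.05, including chaperones with 14 of 24 and translation factors with 21 of 42. None of 22 interferon genes was bound, a share not told apart from that of the rest (Fisher's exact test, adjusted p = 0.626). Within canonical MYC targets and ribosome biogenesis together, 38 of 66 bound and 25 of 48 unbound genes fell (Fisher's exact test, two-sided p = 0.573).

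ATAC-seq asks whether open chromatin changes by 24 h. The DMSO libraries had 38881 ± 11367 peaks and the dTAG47 libraries 35673 ± 6335 (SD, n = 3), and the exact permutation test gave a two-sided p of 0.7, where 0.1 is the smallest possible. Regions open in at least 2 of 3 DMSO libraries numbered 31346, of which 80.5% overlapped those of dTAG47, and 86.1% of the 29683 regions of dTAG47 overlapped those of DMSO. The mean Jaccard index was 0.489 within and 0.496 between treatments (exact permutation test, one-sided p = 0.5, smallest possible 0.1). Regions found in all 3 DMSO libraries and in no dTAG47 library numbered 229, and the reverse 129, while other sets of 3 libraries gave between 22 and 988. Of the 1068 MYC regions, 92.9 ± 3.43% had an ATAC peak in DMSO and 93.1 ± 1.90% after dTAG47 (exact permutation test, two-sided p = 0.9). With these numbers of libraries none of these tests could give a p under 0.1, so they cannot show whether called peaks differ at 0.05.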

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

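Chosen only after the results were seen were the tests for RNA of DTMYC cells in a parental library, for another cell line behind a label, for peaks near assembly gaps, for the peaks after dTAG47 split by overlap with DMSO, and the splits of the parental libraries alone for the interaction.

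The response to dTAG47 differed between the lines by the interaction test, a difference between groups, for 159 genes. Of 100 splits of the libraries drawn at random, the real one included, 3 gave as many genes, with 919 in the highest other, but this excludes nothing, because the 91 splits that mix the DTMYC groups called 0 genes each. With the DTMYC groups kept whole, 7 of the 20 splits of the parental libraries gave as many, the real one included, and the highest other gave 2469. Chance is therefore not excluded for the number of genes, and each of these splits still holds the response of DTMYC cells. The splits with 919 and 2469 genes set parental DMSO libraries 1 and 2 and dTAG47 library 1 against the other 3. This grouping called 1358 genes within parental cells, which points to a structure among the parental libraries. Deviations of the first 3 from their groups followed GC content with a Spearman's rho of 0.60, 0.63 and 0.44. For DMSO library 3 and dTAG47 libraries 2 and 3 it was −0.74, −0.04 and −0.40. Values within a group are not independent, and the cause was not tested. Genes with a higher response in DTMYC cells were ZNF117 (difference of the log2 responses 1.48), SULT1A1 (1.42), TJP3 (1.33), C7orf60 (1.20), TM7SF2 (1.07), ACAT2 (0.71), SLC1A4 (0.68), CDKN2C (0.63), KRT8 (0.54) and EPCAM (1.84, at under 1 CPM in DTMYC cells). Genes with a lower response were POM121C (−1.33), DDN (−1.20), NEFH (−1.12), TERT (−1.04), MATK (−0.92), HK2 (−0.57), TCOF1 (−0.62), MYBBP1A (−0.76), NOP56 (−0.56), RRP1B (−0.67), NOL6 (−0.63), TSR1 (−0.55), GRPEL1 (−0.46), GLDC (−0.47), CYFIP2 (−0.49), MNT (−0.61), NR4A1 (−0.76), FOSL1 (−0.85), FKBP4 (−0.64), STC2 (−1.96, at under 0.1 CPM in parental DMSO) and SLC7A5 (−0.59). ZNF117, SULT1A1 and POM121C share reads with near-identical copies.

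The same test called 16 gene lists, and 16 of 100 splits gave as many, with 22 in the highest other, and with the DTMYC groups kept whole all 20 did, so chance is not excluded for the number of lists. Those that held with an estimated correlation were canonical MYC targets (median difference −0.36), ribosome biogenesis (−0.30), RNA polymerase I and III machinery (−0.17) and cholesterol synthesis (0.25). The others, each with limma's adjusted p with an estimated correlation, were immediate early genes (−0.24, p = 0.0923), purine and pyrimidine synthesis (−0.13, p = 0.0804), mitochondrial import (−0.15 with a mean of 0.02, p = 0.0785), interferon response (0.51, p = 0.0923), SWI/SNF subunits (−0.10, p = 0.0923), chaperones (−0.10, p = 0.117), CDK inhibitors (0.20, p = 0.0785), MYC network members (−0.0712, p = 0.0785), serine metabolism (−0.17, p = 0.0817), translation factors (−0.059, p = 0.0919), DNA replication (−0.0497, p = 0.0841) and mitochondrial ribosomal proteins (−0.0259, p = 0.382).

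For contrasts of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In DTMYC cells 1 of 10 splits, the real one, called as many as 1167 genes (highest other 0) and 23 lists (highest other 18), and the bound genes had a p of 6.74e-17 in 1 of 10 (smallest other 1.57e-11). For the baseline 1 of 10 splits gave 9818 genes (highest other 0) and 6 of 10 gave 6 lists (highest other 8). In parental cells 1 of 10 gave 9 lists (highest other 8), but 2 of 10 gave as many as 17 genes, and the other of these called the 1358 above.

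Parental DMSO library 3 stood apart in its group, with a mean correlation of 0.982 and deviations that followed GC content with a rho of −0.74. RNA of DTMYC cells in this library is argued against, since 19 genes at least 20 times higher in DTMYC cells had a median excess of 0.409% of their DTMYC level (quartiles −0.0860 and 1.64). A bias by GC content and gene length stays open, because offsets raised the mean correlation to 0.991, above the bound of 0.99 set for excluding it and below the 0.995 of the other groups. No biological explanation was tested, since the labels give this library the same treatment as the other parental DMSO libraries.

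The baseline difference between the lines of 9818 genes followed GC content with a rho of −0.44. GC content and length as the whole cause is argued against, since 77.6% of these genes were called in the same direction after offsets. Another cell line behind one of the labels stays open, because 20 genes were at 20 CPM or more in parental and under 0.1 CPM in DTMYC cells, such as ATP10A, GABRA5, BTBD11, RHOBTB1 and GAS7, and 0 the other way. A change during derivation of the DTMYC line, which the design names, stays open as well and was not tested.

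Peaks still called after dTAG47 formed 507 regions, of which 32.3% had a CACGTG near the midpoint and 27.0% lay near an assembly gap or off the numbered chromosomes and X. MYC left on its sites may account for part of them, since the first share lay above the 2.52% of flanks. Calls in repeats beside gaps stay open, because the second share lies between the bounds set for that test. The shares were 39.5% and 10.7% for the 365 regions that overlap a DMSO peak and 5.43% and 69.0% for the 142 that overlap none, which decides neither explanation, because DMSO peaks themselves are rich in CACGTG and seldom near gaps. IgG samples, which measure such background, were not analysed here.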

How the results depend on the processing

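Offsets for GC content, the DTMYC contrast without parental DMSO library 3 and PRO-seq genes at an unadjusted p under 0.05 were chosen after seeing the data. At these depths the promoter-proximal and pausing tests recovered the fewest simulated 2-fold changes, 47.8% and 5.97%. For the changed values below the cause was not tested, except where a minimum fold acts by construction. The bound genes were lower in RNA-seq of DTMYC cells and in PRO-seq gene bodies in the 5 alternatives run for each, of which 1 lost its call in PRO-seq as given below, and none was run for the other RNA-seq contrasts. The next numbers cover all genes selected for naming, of which the text names only a part. Of their results 5764 were the same, 152 became significant, 591 were no longer past the threshold and 3 turned direction. Over lists these numbers were 1773, 87, 119 and 5. Where neither fit passed the threshold a result counted as the same, so turns of direction among those are not in these numbers. The test of genes called in PRO-seq among DTMYC mRNA changes by camera was not run on the calls of the main edgeR fit, as there were none.

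DTMYC genes numbered 1167, and 3355 with GC and length offsets (1123 shared), 4593 with only the 6 libraries of the contrast and 65 at 2-fold. Parental genes numbered 17, and 7 with DESeq2 size factors, 85 with total counts, 310 with the DESeq2 test, 75 with a filter at 1 CPM, 724 with GC offsets, 0 with only 6 libraries (881 at an unadjusted p under 0.05) and 0 at 2-fold. Interaction genes numbered 159, and 63 with DESeq2 size factors, 555 with the DESeq2 test, 102 with no filter, 2055 with GC offsets and 28 at 2-fold. Baseline genes numbered 4012 at 2-fold. PRO-seq gene bodies had 67 genes with the DESeq2 test and 2 with no filter, and promoter-proximal regions 2 and 2.

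The replicate number as a block was checked against the deviations of the libraries. Same-numbered libraries correlated at 0.08, −0.01 and −0.05 in DTMYC cells, 0.32, 0.05 and 0.37 in parental cells, 0.18, −0.20 and −0.12 across lines, and 0.64 in gene bodies and 0.35 in promoter-proximal regions of PRO-seq (2 pairs each). In neither line did every RNA-seq library correlate best with its own number. In PRO-seq each did, but with 2 libraries per group the deviations within a group mirror each other. Both pairs therefore give the same single value for each region. No label says what the numbers share, so the numbers were not taken to pair the libraries in either assay. With the block 27 parental (14 rising and 13 falling), 263 interaction, 4360 gene body, 262 promoter-proximal and 10 pausing genes were called, and the other counts of genes stayed within 1.5 times.

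With an estimated correlation 14 lists were called in DTMYC cells, 1 in parental cells, 4 in the interaction, 0 at baseline and 0 in PRO-seq, and the MYC-bound genes in PRO-seq, at −0.22, were no longer past the threshold (p = 0.149). With fry 28 lists were called at baseline and 0 in PRO-seq. MYC network members turned direction at baseline with fry (adjusted p 0.00305). GARS (−0.0875 ± 0.12) and CALR (0.0864 ± 0.06) turned direction at baseline with GC offsets and no longer passed.

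ATAC-seq regions of DMSO shared with dTAG47, and the reverse, were 85.8% and 88.4% at −log10 q of at least 5, 73.6% and 77.8% at 50% reciprocal overlap, and 84.3% and 83.2% when all 3 libraries were required. Genes called in PRO-seq and also in DTMYC mRNA numbered 47 with DESeq2 and 404 at an unadjusted p under 0.05, against 0 with the main edgeR fit.

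The mean share of MYC regions kept after dTAG47, 10.8%, was 5.52% at 50% reciprocal overlap and 3.62% to 7.59% without 1 DMSO library. In PRO-seq 15 lists were called with no filter, all lower.

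With 1 library left out, genes called ranged from 329 to 3951 in DTMYC cells, 0 to 2718 in parental cells, 5 to 2417 for the interaction, 9128 to 11008 at baseline, 5 to 44 in gene bodies and 1 to 5 in promoter-proximal regions. Lists called stayed at 19 to 23, 8 to 13, 14 to 19 and 5 to 6 in the RNA-seq contrasts in this order and 16 to 17 in PRO-seq. The highest DTMYC, parental and interaction counts all came without parental DMSO library 3. Of 111 genes selected for naming in DTMYC cells, of which the text names only a part, between 26 and 50 lost their call without one of the 6 DTMYC libraries. NCL turned direction in parental cells without DMSO library 3 (0.25 ± 0.08, adjusted p 0.0367), where the values without 1 library ranged from −0.14 to 0.25. In PRO-seq, mitosis turned to lower without DMSO library 2 (adjusted p 0.515) and without dTAG47 library 1 (0.0673), and cholesterol synthesis likewise (0.946 and 0.271). Without dTAG47 library 2 both were higher at 2.97e-14 and 2.60e-10, the other ends of these ranges. ATAC-seq sharing ranged from 66.1% to 93.3% and, for dTAG47 regions in DMSO, from 66.4% to 94.2%. A group of 1 PRO-seq library was assumed to vary like the other group.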

Other observations

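The share of bound genes on any list was tested, and the stretch on chromosome 22 described, only after the results were seen.

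On chromosome 22, between BCR and SPECC1L, 19 genes over a stretch of 1006.57 kb (hg19, about 23660200 to 24666800) had at most 28 gene body counts over the 4 PRO-seq libraries together. SMARCB1, a core subunit of the SWI/SNF remodeller whose loss marks rhabdoid tumours, had 2 counts and CABIN1, an inhibitor of calcineurin, 5, whereas the flanking genes BCR and SPECC1L had 20759 and 23878. GGT5, C22orf43 and the genes of glutathione transfer GSTT1 and GSTT2 lie in the same stretch.

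The hypothesis that the nascent change at 4 h carries over to the mRNA change at 24 h in DTMYC and not in parental cells was tested by the difference of Spearman's rho across genes, which was 0.548, above the 0.1 set beforehand. This is consistent with the hypothesis, which stays one because no PRO-seq data of parental cells were used here.

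The hypothesis that MYC-bound start sites fall mainly in genes of the lists was tested by the odds ratio of canonical MYC targets among bound genes, which was 29.8 (Fisher's exact p = 1.19e-31). Bound genes were enriched in these targets, and 258 of the 993 were on any of the 31 lists (26.0%, binomial 95% interval 23.3 to 28.8). Most bound genes thus lay outside the lists. The number of genes on the lists caps this share, so it does not test the word mainly, and no conclusion is drawn from it.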
